A study of Homo sapiens with 4 samples.

How the data were processed

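Single-cell RNA was measured with the 10x Genomics 5' gene expression assay in CD8+ T cells sorted from blood and tumor of 2 patients with melanoma, 1 library per patient and tissue. The deposited counts are raw UMI counts per gene and cell, which the authors made with Cell Ranger 3.1.0 against GRCh38, per the file headers and labels. The annotation release, the cell calling settings and any later cell filter are not given in the sources used here. The tables hold 33538 features and 24111 barcodes, each with 500 or more UMIs. Gene coordinates were taken from GENCODE 29 on GRCh38 by gene ID.

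Cells with 500 or more UMIs, 300 or more genes and a mitochondrial share under 10% were kept, 17091 in all. Cells were clustered with scanpy 1.11.5 (2000 variable genes, 30 principal components centred within patient, 15 neighbours, Leiden from igraph 0.11.9 at resolution 0.6). The clusters served to find cells other than T cells, and sizes of T cell clusters were not compared. Clusters with CD3 transcripts in 90% or more of their cells were called T-like, and other clusters took a name from fixed marker lists where 3 or more markers were detected in 10% or more of the cells and the leading genes did not go against it. Doublet calling with scrublet marked 2 cells, so doublets stayed in.

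UMIs were summed over the cells of each library, since libraries and not cells are the replicates. The sums were tested with edgeR 4.0.16 in R 4.3.3 (TMM, filterByExpr, quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), with limma 3.58.1 for the lists and DESeq2 1.42.0 as the alternative. V, D and J segments of T cell receptors and immunoglobulins were left out of the tests. The labels name the patient of each library but state no model. Tumor and blood were compared without the patient as a block, and with it as an alternative. The main test thus leaves the pairing out. Its adjusted p-values are the ones printed for this comparison unless another setting is named. After each tissue's mean was taken off, the 2 libraries of a patient had a correlation of 0.241 across 12900 genes. With 2 libraries per tissue, this compares the difference between the patients in blood with that in tumor. Genes are not independent replicates. An error after ± is a standard error for log2 ratios and an SD for levels and shares. A level is in CPM, the counts scaled to a common library total, and its fitted log2 ratio has edgeR's default prior count of 0.125, against 2 for the log2 ratios of each patient, so the fitted ratio of a gene near 0 in 1 group can lie outside both.

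A list test used camera with a correlation preset to 0.01, adjusted over 23 lists, with an estimated correlation and fry as alternatives. With an estimated correlation camera takes its p-value from the residual degrees of freedom, 2 in the main fit and 1 in the pair fits. With a preset correlation it uses a number near that of the genes tested. A call lost with an estimated correlation can thus come from either change. The 16 T cell lists were inhibitory receptors and exhaustion, naive and central memory, circulating effector, cytotoxic granules, tissue residency, chemokine and homing receptors, cytokines and chemokines, activation and costimulation, immediate early, heat shock and chaperones, proliferation, interferon response, glycolysis and hypoxia, NK receptors, T cell transcription factors, and MAIT and gamma-delta T. The other 7 held markers of B and plasma, myeloid, NK, CD4 and regulatory T, melanocyte and melanoma, fibroblast and endothelial, and erythroid and platelet cells. Genes were named by a rule: the 14 largest rises and 14 largest falls past the test with a mean of 20 CPM or more and 1 direction in both patients, and per list the 3 largest called members or, with none called, the 2 with the highest level. V pair comparisons took the 8 largest in each direction. Variable, sex-linked and mitochondrial genes were not named.

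Shares of cells with a UMI of 28 key genes were taken after thinning each cell to 2000 UMIs, with exact Clopper-Pearson intervals at 95%, and compared with an exact two-sided permutation test. Intervals and the floor of 3 counts cover counting error only. A V segment was called in a cell with 2 or more UMIs and 80% or more of its chain's UMIs. A pair of alpha and beta V segments was expanded with 1% or more of a tumor's cells with a pair, 10 or more cells, and 3 or more times the product of its V shares. Cells with and without an expanded pair were summed per library and tested with the library as a block, which leaves 1 residual degree of freedom. Different clones can share a V pair, so pairs are a proxy.

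On simulated data with 100 genes each changed 2-fold and 4-fold in 10 draws, the test of tumor against blood recovered 0.4% and 18.6% of them, and 26.4% of its calls were unchanged genes, above the nominal rate. With the block it recovered 4.7% and 58.1% (9.38% unchanged), in T-like clusters 6.7% and 68.4% (9.95%), and in the pair tests 65.5% and 93.6% in tumor (5.63%) and 37.6% and 80.8% in blood (3.27%). The simulated counts used the spread fitted to these data and held no differences between patients or V pairs. The rates therefore do not test that spread. Default settings were kept. Alternatives changed the normalization, the low-count and cell filters, the doublets, the cells used, the depth, the V pair rules, the block, the tool and, for tumor against blood, each library in turn. Lists, tests, naming rules and most alternatives were set before the data were examined; the others are named with their results.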

Results

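Transcripts were counted in single CD8+ T cells, the cytotoxic branch of T lymphocytes, sorted from the blood and from the tumor of 2 patients with melanoma. Each patient gave 1 blood and 1 tumor library, so each tissue had 2 libraries. The libraries held 7281 and 6060 cell barcodes from blood and 7013 and 3757 from tumor (patients 1 and 2). Their totals were 26590174, 18524143, 22676088 and 18105045 UMIs, in the same order, with medians of 3460, 3046, 2986 and 3282 UMIs per barcode. A UMI is a tag that marks 1 captured transcript. The filter on genes and mitochondrial share kept 6038 and 3603 blood cells and 4519 and 2931 tumor cells. The mitochondrial limit alone removed 17.1% and 40.5% of the blood barcodes and 35.5% and 20.8% of the tumor barcodes.

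Most cells carried T cell transcripts, but the tumor library of patient 2 also held melanoma-like and myeloid-like cells. Of the 17091 cells kept, 16143 fell in 13 T-like clusters and 948 in 5 other clusters. Outside the T-like clusters lay 2.82% and 2.78% of the blood cells and 3.94% and 17.1% of the tumor cells, which held 2.53%, 2.96%, 4.25% and 37.2% of the UMIs. A melanoma-like cluster led by S100A1, TIMP3, PMEL and MLANA had 168 cells, all in the tumor library of patient 2, at a median of 29080 UMIs per cell. These cells gave 29.9% of that library's UMIs. A myeloid-like cluster led by IL1B, CXCL2 and LYZ held 4 and 58 blood cells and 11 and 264 tumor cells. An NK-like cluster held 138 and 27 blood cells against 0 and 2 tumor cells, and a cluster called plasma-like for its leading genes held 15 and 13 blood cells and 15 and 18 tumor cells. Its leading genes were seen in few of these cells (MZB1 in 24.6%, IGHG1 in 18.03%, IGKC in 13.1%), CD3 and CD8 transcripts in 44.3% each, and its median was 813 UMIs. Over all cells kept, IGKC had 14 UMIs in blood and 4586 in tumor. The name is thus not borne out for the blood cells of this cluster, which had medians of 591 and 707 UMIs. The fifth cluster, led by KIT, FAM30A and TCF4, stayed unnamed and held 13 and 2 blood cells and 152 and 48 tumor cells. The sort was for CD8, and the T-like clusters were defined by CD3 transcripts in 90% or more of their cells, a threshold set after seeing the data.

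**Figure D1:**
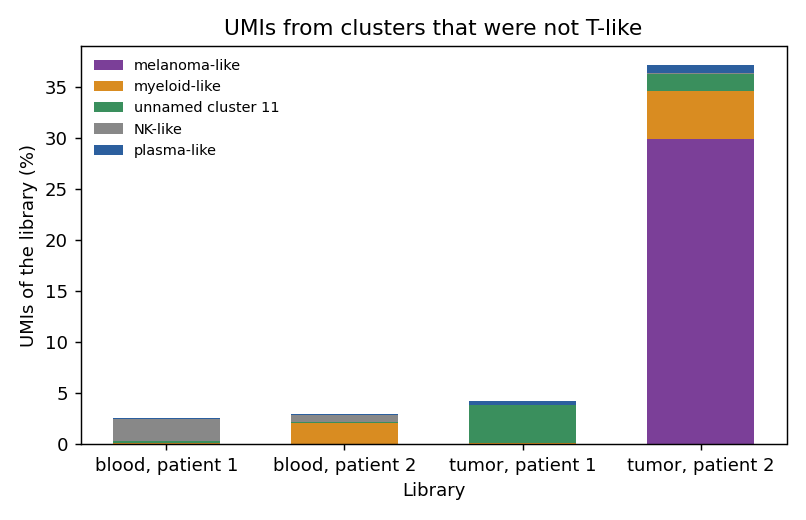
Share of each library's UMIs (vertical axis, %) that came from cells in clusters that were not T-like, for the 4 libraries (horizontal axis). Stacked colors mark the clusters; the bar of the tumor library of patient 2 reaches 37.2%, of which melanoma-like cells gave 29.9%, and the unnamed cluster is the one led by KIT.

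The main comparison asked which transcripts differ between cells sorted as CD8+ T cells from tumor and from blood. Its sums held all cells kept, also those outside the T-like clusters. Among the fixed lists, 16 of 21 exhaustion genes, 16 of 28 cell cycle genes, 12 of 28 immediate early genes, 7 of 23 cytokine genes and 6 of 20 heat shock genes were higher in tumor, and 5 of 20 circulating effector and 2 of 17 NK receptor genes were lower. Each of these lists lost its call with an estimated correlation (adjusted p from 0.0826 to 0.273). For exhaustion, cytokines and NK receptors that correlation was -0.0369, -0.0109 and -0.00312, below the preset 0.01. A higher correlation cannot explain the loss in these lists. For the others it was 0.0866 to 0.374. With an estimated correlation camera also rests on the 2 residual degrees of freedom of the fit. With the preset correlation it uses a number near that of the genes tested. The lost calls are thus no measure of gene correlation alone. In the edgeR quasi-likelihood test on UMI sums of the 4 libraries, 349 genes were higher and 41 lower in tumor at a Benjamini-Hochberg adjusted p under 0.05, of 12900 tested. With the patient as a block, since each patient gave both tissues, the counts were 1200 and 467, and DESeq2 called 1128 and 442. In the T-like clusters alone they were 1056 and 402 of 12374, and 341 of the 349 and all 41 were among them. The share of calls that were higher was 89.5% over all cells, 72.0% with the block and 72.4% in T-like clusters. Of the 23 lists, camera with a preset correlation called 17, 12 higher and 5 lower, and with an estimated correlation it called 0 (7 at an unadjusted p under 0.05), while fry called 8. In T-like clusters camera called 19, and 0 with an estimated correlation (5 at an unadjusted p under 0.05). The edgeR p-values rest on the spread between 2 libraries per tissue, from 2 patients, and on a spread shared across genes. The main fit had 2 residual and 3.72 prior degrees of freedom, and the fit with the block 1 and 12.5. Camera with a preset correlation compares a list's genes with the other genes. Its small p-values are no measure of the spread between libraries. Any difference in handling went with tissue in this design, so these differences are between blood and tumor samples as prepared.

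The count depended on which library was left out. Without the blood library of patient 1 or the blood library of patient 2, edgeR called 0 genes, with 1378 and 1150 genes at an unadjusted p under 0.05, so none of the genes named for this comparison passed there. Without the tumor library of patient 1 the counts were 2255 higher and 741 lower, and without that of patient 2 they were 685 and 158. In T-like clusters, calls stayed in each such fit, from 385 higher and 81 lower (without the blood library of patient 1) to 964 and 292 (without the tumor library of patient 1). They were 529 and 116 without the blood library of patient 2, and 631 and 129 without the tumor library of patient 2.

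The list of inhibitory receptors and exhaustion markers, fixed before the values were seen, had the largest median rise of the 16 T cell lists. Of its 21 genes, 16 rose and 0 fell, and all 21 rose when adjusted over the list alone, with the patient block and in T-like clusters. The median log2 ratio of tumor over blood was 5.07 (4.44 in patient 1, 4.96 in patient 2), and 5.53 in T-like clusters. CXCL13, a chemokine that attracts B cells (ENSG00000156234, chromosome 4, 77511753 to 77611834 in GRCh38), stood at 0 and 0.391 CPM in blood and 299.5 and 1698 CPM in tumor (log2 12.55 ± 1.59, adjusted p = 0.0314). VCAM1, an adhesion molecule (ENSG00000162692, chromosome 1, 100719742 to 100739045), rose from 1.25 ± 1.44 to 177 ± 38.1 CPM (SD, n = 2, log2 7.05 ± 0.93, adjusted p = 0.0316). MYO7A, an unconventional myosin (ENSG00000137474, chromosome 11, 77128264 to 77215241), had 1 UMI in blood and 829 in tumor, a ratio of 878 (95% counting interval 157 to 34739, adjusted p = 0.0197). The list passed camera with the preset correlation (adjusted p = 2.4e-50), and gave adjusted p = 0.0826 with an estimated correlation.

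Cytokine, costimulation and transcription factor genes rose in part. Of 23 cytokine and chemokine genes 7 rose and 0 fell (12 and 0 adjusted over the list alone; 14 higher and 2 lower with the block; 12 and 1 in T-like clusters). IFNG, the type II interferon (ENSG00000111537, chromosome 12, 68154768 to 68159747), rose from 6.63 ± 0.530 to 206 ± 42.6 CPM (SD, n = 2, log2 4.96 ± 0.34, adjusted p = 0.0175). CSF2, which encodes GM-CSF, had 2 UMIs in blood and 154 in tumor, a ratio of 81.6 (counting interval 22.2 to 679.8, adjusted p = 0.0425). In T-like clusters CSF2 had 2 and 63 UMIs, a ratio of 40.2 (counting interval 10.7 to 339, adjusted p = 0.0128). Of 22 activation and costimulation genes 5 rose (13 over the list alone, 12 with the block, 14 in T-like clusters) and 0 fell. They included the costimulatory receptors TNFRSF9 (log2 5.68 ± 0.41), TNFRSF18 (log2 4.11 ± 0.35) and ICOS (log2 3.61 ± 0.39). Of 28 T cell transcription factors 6 rose and 0 fell (9 and 2 adjusted over the list alone; 9 and 4 with the block; 10 and 1 in T-like clusters), among them ETV1 (log2 6.12 ± 0.43), ID3 (log2 5.38 ± 0.74) and TOX2 (log2 5.07 ± 0.65). Median log2 ratios were 1.70, 1.38 and 0.46. The lists passed camera (adjusted p = 9.6e-09, 2.3e-11 and 7.9e-04), with adjusted p = 0.150, 0.158 and 0.358 with an estimated correlation. The transcription factor list was lost without the blood library of patient 1 (adjusted p = 0.0842) and without the tumor library of patient 1 (adjusted p = 0.355).

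Part of the immediate early genes, which respond within minutes to stimulation, and of the heat shock genes were higher in tumor. Of 28 immediate early genes 12 rose and 0 fell (21 adjusted over the list alone, 22 with the block, 20 in T-like clusters), at a median log2 ratio of 2.75. NR4A1, an orphan nuclear receptor induced by T cell receptor signals (ENSG00000123358, chromosome 12, 52022832 to 52059507), rose from 1.65 ± 1.10 to 237 ± 132 CPM (SD, n = 2, log2 7.21 ± 0.76, adjusted p = 0.0257). ATF3, a stress-induced transcription factor, also rose (log2 6.18 ± 1.07, adjusted p = 0.0490), and EGR3 went from 2 to 165 UMIs, a ratio of 87.4 (counting interval 23.8 to 728, adjusted p = 0.0490). In T-like clusters EGR3 had 2 and 40 UMIs, a ratio of 25.5 (counting interval 6.62 to 218, adjusted p = 0.0358). NR4A1 and ATF3 had log2 7.01 and 6.18 there. Of 20 heat shock genes 6 rose and 0 fell (15 over the list alone, 12 with the block, 13 in T-like clusters), at a median of 1.40. The inducible HSP70 genes HSPA1A (ENSG00000204389, chromosome 6, 31815464 to 31817946) and HSPA1B (ENSG00000204388, chromosome 6, 31827735 to 31830255) rose (log2 6.42 ± 0.84 and log2 7.60 ± 1.12). They are near-identical copies, so the split of reads between them is uncertain. HSPA6 rose as well (log2 6.57 ± 1.10, adjusted p = 0.0470). Both lists passed camera (adjusted p = 1.2e-25 and 2.6e-11), with adjusted p = 0.150 and 0.273 with an estimated correlation.

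Part of the cell cycle genes were higher in tumor as well. Of 28 proliferation genes 16 rose and 0 fell (28 adjusted over the list alone, 26 with the block, 27 in T-like clusters), at a median log2 ratio of 3.20. Cyclin A2 (CCNA2, ENSG00000145386, chromosome 4, 121816444 to 121823933) rose from 0.606 ± 0.304 to 19.3 ± 0.257 CPM (SD, n = 2), with CDK1 (log2 4.88 ± 0.60) and AURKB (log2 4.23 ± 0.51), kinases of mitosis. In the interferon response list, 1 gene rose and 1 fell of 32 (the same counts over the list alone; 10 and 1 with the block; 7 and 1 of 31 in T-like clusters). These were OASL, an antiviral protein (log2 3.63 ± 0.63), and SAMHD1, a nucleotide hydrolase (log2 -2.20 ± 0.36). Of 24 glycolysis and hypoxia genes 1 rose and 0 fell (10 over the list alone, 11 with the block, 8 of 23 in T-like clusters), which was the glucose transporter gene SLC2A3 (log2 2.29 ± 0.29). The medians were 0.94 and 1.29. All 3 lists passed camera (adjusted p = 5.8e-35, 2.2e-04 and 2.0e-07), with adjusted p = 0.150, 0.379 and 0.328 with an estimated correlation.

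A minority of the circulating effector and NK receptor genes were lower in tumor. Of 20 circulating effector genes 5 fell and 0 rose (14 adjusted over the list alone, 12 with the block, 9 in T-like clusters), at a median log2 ratio of -1.37. FGFBP2, a secreted protein of cytotoxic lymphocytes (ENSG00000137441, chromosome 4, 15960243 to 15969309), fell from 172 ± 10.0 to 18.2 ± 3.17 CPM (SD, n = 2, log2 -3.24 ± 0.30, adjusted p = 0.0202). S1PR5, a receptor for sphingosine 1-phosphate (ENSG00000180739, chromosome 19, 10512742 to 10517931), and the integrin gene ITGAM fell too (log2 -2.80 ± 0.36 and log2 -2.84 ± 0.46). Of 17 NK receptor genes 2 fell (6 over the list alone, 6 with the block, 7 in T-like clusters) and 0 rose, at a median of -0.70. KLRF1 (ENSG00000150045, chromosome 12, 9827481 to 9845007) fell from 81.5 ± 12.3 to 6.97 ± 0.766 CPM and KLRB1, which encodes CD161, from 429 ± 179 to 90.4 ± 1.78 CPM. NK-like cells made up 2.29% and 0.749% of the blood cells and 0% and 0.0682% of the tumor cells. KLRB1 was also the 1 called gene of 17 in the MAIT and gamma-delta T list (4 lower over the list alone, 4 with the block, 4 in T-like clusters, median -1.03). The lists passed camera (adjusted p = 2.3e-11, 6.7e-06 and 5.1e-04), with adjusted p = 0.150, 0.150 and 0.158 with an estimated correlation.

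Naive and memory genes, homing receptors and granule genes gave fewer calls. None of 20 naive and central memory genes passed, over all genes or over the list alone, at a median log2 ratio of -0.98, although 8 were lower with the block and 1 was higher and 3 were lower in T-like clusters. IL7R, the interleukin 7 receptor, had log2 -1.19 ± 0.30, adjusted p = 0.101 (adjusted p = 0.0179 with the block), and KLF2 had log2 -1.04 ± 0.43, adjusted p = 0.224. Of 18 tissue residency genes 2 rose (11 over the list alone, 11 with the block, 9 of 17 in T-like clusters) and 0 fell, at a median of 2.43. They were the chemokine receptor gene CXCR6 (ENSG00000172215, chromosome 3, 45940933 to 45948353, log2 3.58 ± 0.62, adjusted p = 0.0490) and RGS2 (log2 2.68 ± 0.37). Of 23 chemokine and homing receptors 2 rose, CXCR6 and GPR183 (log2 2.58 ± 0.44), and 1 fell, S1PR5, at a median of 0.10 (3 and 1 over the list alone, 4 and 4 with the block, 4 and 2 of 24 in T-like clusters). The camera test of this list pointed down, against the sign of its median (adjusted p = 0.972). Of 18 cytotoxic granule genes SERPINB9, an inhibitor of granzyme B, rose (log2 2.21 ± 0.30) at a list median of 0.27 (6 higher and 1 lower over the list alone, 6 and 1 with the block, 6 and 1 in T-like clusters). Camera gave adjusted p = 1.8e-04 for the naive, 5.3e-07 for the residency and 0.203 for the granule list. With an estimated correlation these were adjusted p = 0.328, 0.328 and 0.379; the granule list passed in T-like clusters (adjusted p = 0.0157, and adjusted p = 0.247 with an estimated correlation).

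**Figure D2:**
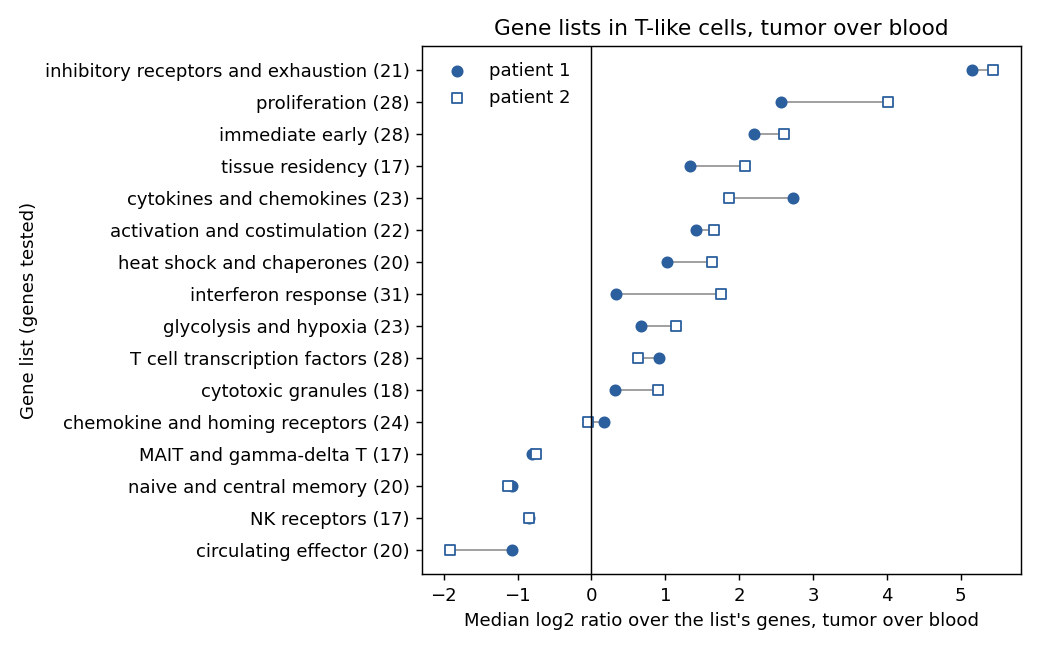
Median log2 ratio of tumor over blood (horizontal axis) over the tested genes of each T cell list (vertical axis, number of genes in brackets), in T-like clusters. Circles stand for patient 1 and squares for patient 2, joined by a line; the exhaustion list lies at 5.15 and 5.44, and the circulating effector list at -1.07 and -1.92.

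Markers of other cell types differed between the libraries too. Of 9 B and plasma cell genes 3 rose (6 over the list alone, 7 with the block, 3 of 7 in T-like clusters), at a median log2 ratio of 4.37. They were the immunoglobulin chain gene IGKC (log2 8.05 ± 1.08), JCHAIN (log2 7.89 ± 0.97) and MZB1 (log2 4.37 ± 0.35). In T-like clusters the median of the list was 1.67 (1.27 in patient 1, 2.32 in patient 2) over 7 genes. There IGKC had 0 UMIs in blood and 35 in tumor, at least 14.9-fold higher with a floor of 3 counts over the group (adjusted p = 0.020), and JCHAIN was too low to be tested. Of 11 CD4 and regulatory T cell genes 2 rose (the same over the list alone, 4 with the block, 3 of 9 in T-like clusters, median 0.47), CTLA4 (log2 4.71 ± 0.40) and TNFRSF4 (log2 2.71 ± 0.45), which activated CD8+ T cells also express. This list passed camera (adjusted p = 0.0131; adjusted p = 0.328 with an estimated correlation), but not without the blood library of patient 1 (adjusted p = 0.305) or the tumor library of patient 1 (adjusted p = 0.0528). The plasma list passed as well (adjusted p = 3.7e-09; adjusted p = 0.150 with an estimated correlation). Of 9 NK cell genes KIT rose (log2 4.52 ± 0.60) and KLRF1 fell, at a median of -0.31 (1 higher and 1 lower over the list alone, 2 and 1 with the block, 0 and 2 of 8 in T-like clusters, camera adjusted p = 0.107). The list passed, downward, without the tumor library of patient 2 (adjusted p = 0.00636) and in T-like clusters (adjusted p = 0.0335; adjusted p = 0.247 with an estimated correlation), but not in T-like clusters with the block (adjusted p = 0.110). KIT led the unnamed cluster that held 152 and 48 tumor cells.

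None of 15 myeloid, 2 melanocyte, 3 fibroblast and endothelial and 4 erythroid and platelet genes passed over all genes. Over the list alone 0 myeloid genes passed, 1 melanocyte gene and 2 fibroblast genes were higher and 3 platelet genes lower; with the block 5 myeloid genes were higher and 3 lower, 1 melanocyte and 2 fibroblast genes higher and 3 platelet genes lower. In T-like clusters 0 of 5 myeloid genes passed, 1 melanocyte and 2 fibroblast genes were higher and 4 platelet genes lower. Median log2 ratios were 0.32, 5.88, 1.47 and -6.23, and camera gave adjusted p = 0.663, 0.231, 0.163 and 4.6e-05 (0.273 for the platelet list with an estimated correlation). The melanocyte list passed without the blood library of patient 1, that of patient 2 or the tumor library of patient 1 (adjusted p = 0.00310, 0.00394 and 1.8e-51). The myeloid list passed upward without the blood library of patient 2 or the tumor library of patient 1 (adjusted p = 0.00817 and 0.00265) and downward without the tumor library of patient 2 (adjusted p = 0.00238). The platelet list, which passed with all libraries, had a median of -4.40 with 2 genes put at their bound. Without the blood library of patient 1 it was lost (adjusted p = 0.183). PF4, a platelet chemokine, had 153 UMIs in blood and 0 in tumor, at least 48.1-fold lower with a floor of 3 counts over the group (adjusted p = 0.0660, 3.9e-04 with the block). PPBP had log2 -1.45 ± 1.73, adjusted p = 0.663 (in T-like clusters 551 UMIs in blood and 0 in tumor, at least 144-fold lower with the same floor, adjusted p = 0.0125). The myeloid genes CST3 and S100A8 had log2 2.05 ± 1.06, adjusted p = 0.313 and log2 -1.01 ± 1.93, adjusted p = 0.798 (0.00450 and 0.0253 with the block). In T-like clusters CST3 had log2 -1.24, adjusted p = 0.220 and S100A8 log2 -0.14, adjusted p = 0.959. CST3 was lower in tumor also in T-like clusters with the block, under a 5% mitochondrial share and without the tumor library of patient 2, and S100A8 was higher when thinned and without the blood library of patient 2. SERPINE2 and S100B, in the melanocyte list, stood at 454 and 522 CPM in the tumor library of patient 2 and at 2.86 and 4.06 CPM in that of patient 1 (adjusted p = 0.130 and 0.311; SERPINE2 0.0499 with the block; in T-like clusters SERPINE2 log2 2.55, adjusted p = 0.0471 and S100B log2 -1.56, adjusted p = 0.157). PECAM1 had log2 -0.57 ± 0.48, adjusted p = 0.525 and ACTA2 had log2 1.47 ± 0.32, adjusted p = 0.0744 (0.0246 with the block).

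Of the remaining largest rises, ZBED2, a zinc finger gene (ENSG00000177494, chromosome 3, 111592900 to 111595443), had 0 UMIs in blood and 1686 in tumor, at least 596-fold higher with a floor of 3 counts over the group (adjusted p = 0.0202). GEM, a small GTPase (ENSG00000164949, chromosome 8, 94249253 to 94262350), rose from 0.341 ± 0.0715 to 122 ± 84.1 CPM (SD, n = 2, log2 8.48 ± 0.76, adjusted p = 0.0202), and LMNA, which encodes lamins A and C (ENSG00000160789, chromosome 1, 156082573 to 156140089), from 4.23 ± 0.233 to 407 ± 87.4 CPM (log2 6.58 ± 0.36, adjusted p = 0.0175). In T-like clusters GEM had log2 8.12 and LMNA log2 5.87. Of the tumor UMIs, 2486 of 4508 for GEM and 8237 of 15354 for LMNA lay there. PHLDA1 rose (log2 5.87 ± 0.65, adjusted p = 0.0257), as did CAV1, the gene of caveolin 1 (log2 8.19 ± 1.15, adjusted p = 0.0360; log2 6.27, adjusted p = 0.00821 in T-like clusters). Besides the genes of the fixed lists, the largest falls were APBA2 (log2 -2.54 ± 0.33), FCRL6 (log2 -2.36 ± 0.39), FGR, a Src family kinase (log2 -2.33 ± 0.39), and PTGDR, a prostaglandin D2 receptor (log2 -2.17 ± 0.26). PLEKHA1, ZNF75A, PET117 and ZNF101 had log2 -1.76, -1.74, -1.73 and -1.67. MAPKAPK5-AS1 had log2 -1.66 ± 0.25, but it is antisense to another gene and uncertain where counting did not use strand. Each of the 52 called genes that the fixed rules name went the same way in every alternative in which it was tested. JCHAIN and KIT were not tested in T-like clusters, 12 genes not at 20 CPM, 1 not under a 5% mitochondrial share and 1 not with the CD8 and CD3 gate; 17 of the 52 lost the call without the cell filter, and all 52 without either blood library.

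Shares of cells with a UMI of a key gene were compared at 2000 UMIs per cell. In both patients more tumor than blood cells held transcripts of inhibitory receptors. The share with PDCD1, which encodes PD-1, went from 1.77% ± 0.757 in blood to 18.1% ± 3.87 in tumor (SD, n = 2; unthinned 3.11% ± 0.936 and 27.5% ± 3.93). For HAVCR2 it went from 0.511% ± 0.0628 to 27.1% ± 7.33, for LAG3 from 7.32% ± 1.47 to 49.7% ± 3.79, for TIGIT from 6.13% ± 2.29 to 34.6% ± 1.87 and for CTLA4 from 1.40% ± 0.119 to 35.1% ± 15.5. Unthinned, these were 1.05% ± 0.125 and 37.3% ± 8.12, 12.5% ± 2.30 and 58.4% ± 1.15, 10.4% ± 2.86 and 46.9% ± 1.43, and 2.42% ± 0.189 and 45.4% ± 12.4. CXCL13 was seen in 0 of 5766 and 0 of 3432 blood cells, which allows up to 0.0520% and 0.0874% of cells with a UMI at 3 counts (exact upper bounds 0.0640% and 0.107%; unthinned 0 of 6038 and 1 of 3603 cells), and in 14.8% and 50.1% of the tumor cells (unthinned 18.2% and 49.98%). The granzyme gene GZMB went from 19.9% ± 0.253 to 48.8% ± 21.8 (unthinned 26.5% ± 0.251 and 53.3% ± 17.7) and ENTPD1, which encodes CD39, from 0.469% ± 0.491 to 22.7% ± 12 (unthinned 0.954% ± 0.810 and 32.9% ± 14.3). The share with IL7R went from 46.9% ± 11.2 to 23.9% ± 0.774 (unthinned 58.2% ± 9.26 and 30.1% ± 2.62), that with TCF7, a factor of naive and memory cells, from 23.4% ± 6.47 to 9.04% ± 7.95 (unthinned 37.1% ± 9.0 and 15.8% ± 11.8), and that with FGFBP2 from 18.7% ± 0.657 to 2.97% ± 0.346 (unthinned 24.4% ± 1.20 and 4.72% ± 0.305).

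For each of these genes the 2 blood and 2 tumor libraries did not overlap, and the exact two-sided permutation test gave p = 0.333, the smallest that 2 against 2 libraries allow. Thinning left out 272 and 171 blood cells and 195 and 362 tumor cells. As a background for free RNA, of the 157 melanoma-like cells of the tumor library of patient 2 that were deep enough, 0.637% had a UMI of PDCD1, 1.91% of LAG3, 1.91% of CTLA4, 1.91% of HAVCR2, 3.19% of TIGIT, 3.82% of ENTPD1, 5.10% of GZMB and 8.92% of CXCL13, at the same thinned depth. Before thinning, these melanoma-like cells had a median of 30181 UMIs and the T-like cells of the library that were deep enough 3785, so thinning also thinned the free RNA of these cells and their shares are a low estimate of the background. Of 147 myeloid-like cells there (median 3476 UMIs before thinning), 6.80% had PDCD1, 10.9% LAG3, 12.9% CXCL13, 12.9% GZMB, 16.3% IL7R and 17.7% CD8A, against 79.4% CD8A over all cells. GZMK went opposite ways in the patients, with or without thinning. The thinned shares of ITGAE were 9.96% and 11.4% in blood and 9.62% and 28.3% in tumor, so patient 1 showed no difference beyond counting error (9.19 to 10.8% against 8.76 to 10.5%). Without thinning the ITGAE share was higher in tumor in both patients, 19.1% against 17.6% and 43.4% against 19.96%.

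**Figure D3:**
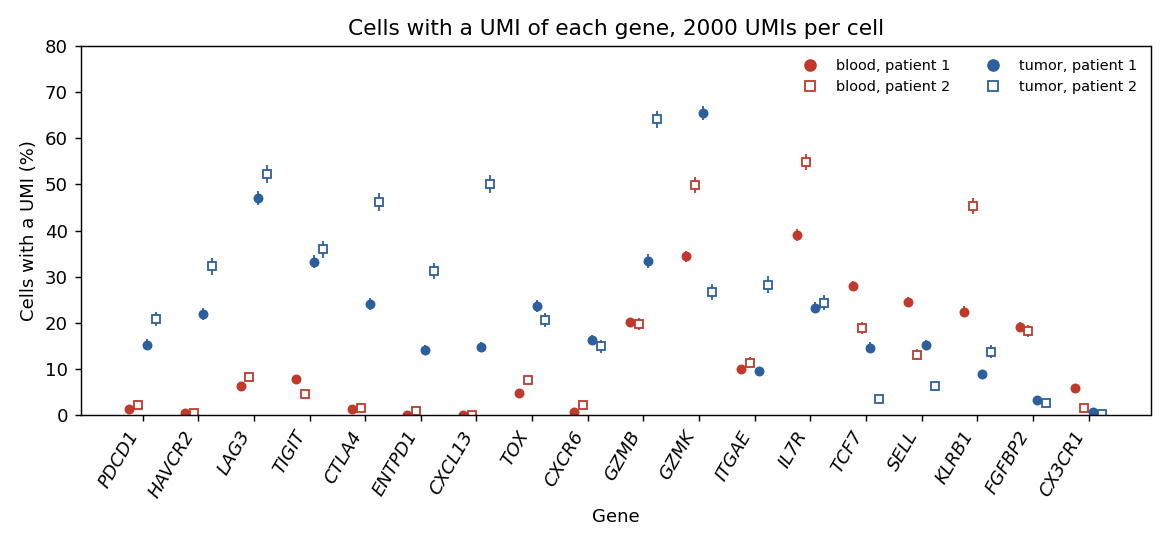
Share of cells with at least 1 UMI of each gene (vertical axis, %) after thinning every cell to 2000 UMIs, for 18 of the 28 key genes (horizontal axis). Points are libraries (blood red, tumor blue, patient 1 circles, patient 2 squares) and bars are exact 95% binomial intervals, which cover counting error only; the tumor points of LAG3 lie at 47.0% and 52.4%, above the blood points at 6.28% and 8.36%.

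The pair of V segments of a cell's T cell receptor chains, read from its UMIs, served as a stand-in for its clone. Tumors were partly made of a few frequent pairs, and 10 of the 15 expanded pairs in patient 1 and 2 of the 9 in patient 2 were also seen in the same patient's blood. A pair could be called in 1729 and 432 blood cells and in 1661 and 873 tumor cells. In tumor, the expanded pairs covered 24.4% (exact 95% interval 22.3 to 26.5) and 51.1% (47.7 to 54.5) of these cells in patients 1 and 2. By the same rule, blood's own expanded pairs covered 43.5% (41.1 to 45.9) and 34.7% (30.2 to 39.4) of blood cells. Of blood cells with a pair, 171 of 1729 (9.89%, 8.52 to 11.4) and 71 of 432 (16.4%, 13.1 to 20.3) carried a pair expanded in the same patient's tumor. The other patient's expanded pairs, taken as a background of chance sharing, were carried by 0.810% (0.443 to 1.35) and 2.08% (0.957 to 3.92). This background held 9 pairs for patient 1 and 15 for patient 2, and it was not matched to each patient's V usage. In each patient 1 pair held most matched blood cells, 60.2% and 98.6% of them, and without it the shares were 4.18% and 0.276%. When an expanded pair had to reach 2% of tumor cells, the shares were 0.347% and 0.231%, against 0.347% and 0% for the other patient's pairs, so patient 1 showed no excess there (6 cells each). When a V segment needed 3 UMIs they were 3.62% and 0% (0 of 142 cells), against 0.285% and 3.52%, so patient 2 showed none. With 1 UMI the share of patient 2 was 33.8%, against 0.150%. Intervals cover counting error only, and these shares were not tested between the patients.

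**Figure D4:**
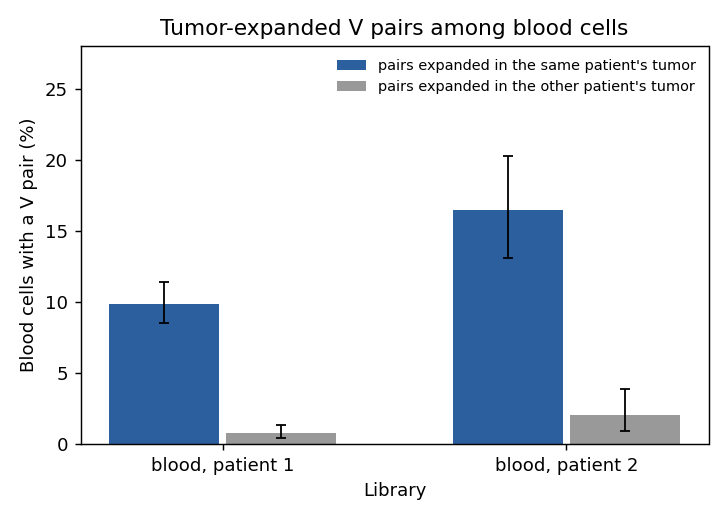
Share of blood cells with a called V pair (vertical axis, %) whose pair was expanded in the same patient's tumor (blue) or in the other patient's tumor (grey), for the 2 blood libraries (horizontal axis). Bars are the shares and whiskers exact 95% binomial intervals; the same-patient shares are 9.89% and 16.4%.

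Within the tumors, cells with an expanded pair were compared with the other cells that had a pair, with the library as a block. Expanded cells held less RNA of some naive and memory genes and of CCL20, a chemokine. The edgeR test called 25 genes higher and 33 lower of 9110. LTB, which encodes lymphotoxin beta (ENSG00000227507, chromosome 6, 31580525 to 31582522), had log2 -1.74 ± 0.15, adjusted p = 7.9e-06, and CCL20 (ENSG00000115009, chromosome 2, 227805739 to 227817564) had log2 -3.12 ± 0.30, adjusted p = 1.8e-05. Lower too were IL7R (log2 -1.83 ± 0.30, adjusted p = 0.00803), CCR7, a lymph node homing receptor (log2 -1.93 ± 0.37), LEF1 (log2 -1.89 ± 0.36), AQP3 (log2 -1.79 ± 0.24), S1PR1 (log2 -1.73 ± 0.31) and MYC (log2 -1.50 ± 0.26). Higher were CXCL3 (log2 1.58 ± 0.22), the histone gene HIST1H3B (log2 1.19 ± 0.18), PIP5K1B (log2 1.03 ± 0.23), LGALS9, which encodes galectin 9 (log2 0.89 ± 0.18), MEF2A (log2 0.85 ± 0.18), AKAP5 (log2 0.81 ± 0.17), SNAP47 (log2 0.68 ± 0.13) and ADGRG1 (log2 0.61 ± 0.11). CXCL3 was a leading gene of the myeloid-like cluster, and among T-like cells it had log2 -0.16. Of 20 naive and central memory genes 6 fell (11 adjusted over the list alone). Of 21 exhaustion genes 3 rose (18 over the list alone). Both lists passed camera with the preset correlation (adjusted p = 1.1e-21 each). With an estimated correlation they gave adjusted p = 0.659, but camera then rests on 1 residual degree of freedom, so this value says little about them. Without the block 0 genes passed in edgeR (81 at an unadjusted p under 0.05), and DESeq2 with the block called 0 and 2; in T-like cells the counts were 2 and 5. That setting kept 1657 of 1661 and 859 of 873 cells, and edgeR's prior degrees of freedom went from 15.7 to 9.02. HIST1H3B, CCL20, AQP3 and LTB passed in T-like cells (adjusted p = 0.0419, 0.00500, 0.0181 and 0.00689), the other 12 named genes did not. Of these 12, CXCL3 alone changed direction, and IL7R, LEF1 and LGALS9 had log2 -1.88, -1.85 and 0.90 there.

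In blood, cells with a pair expanded in the same patient's tumor carried more RNA of some cytotoxic genes and less of most naive and memory genes tested than other blood cells with a pair. The same test called 48 genes higher and 120 lower of 7008. GNLY, which encodes granulysin (ENSG00000115523, chromosome 2, 85685175 to 85698854), had log2 1.11 ± 0.10, adjusted p = 1.6e-22, and CMC1 (ENSG00000187118, chromosome 3, 28241584 to 28325142) had log2 1.39 ± 0.13, adjusted p = 1.0e-24. Higher as well were TRGC2 (log2 2.10 ± 0.39), SKAP2 (log2 1.61 ± 0.36), KLRF1 (log2 1.48 ± 0.21), the chemokine gene XCL2 (log2 1.26 ± 0.24), LILRB1 (log2 1.24 ± 0.36) and BBC3 (log2 1.21 ± 0.32). Lower were LTB (log2 -2.04 ± 0.16, adjusted p = 2.8e-35), CCR7 (log2 -1.99 ± 0.30, adjusted p = 1.4e-08), SERINC5 (log2 -2.60 ± 0.48), TXK (log2 -2.57 ± 0.52), MAL (log2 -2.22 ± 0.35), FOS (log2 -2.06 ± 0.39) and THEM4 (log2 -2.01 ± 0.37). ZNF683 had 3 UMIs in the matched cells, a ratio of 0.0970 to the others (counting interval 0.0199 to 0.286, adjusted p = 9.1e-07). Of 19 naive and central memory genes 13 fell (16 adjusted over the list alone). Of 18 cytotoxic granule genes 7 rose (10 over the list alone). The lists passed camera with the preset correlation (adjusted p = 4.0e-50 and 1.1e-18). With an estimated correlation they gave adjusted p = 0.633, but camera then rests on 1 residual degree of freedom, so this value says little about them. Without the block 0 genes passed in edgeR (207 at an unadjusted p under 0.05), and DESeq2 with the block called 6 and 5. In T-like cells 3 and 2 passed, among them CMC1 and GNLY (log2 1.39 and 1.11, adjusted p = 0.00585 each). That setting removed few cells (kept 1722 of 1729 and 430 of 432, and all 171 and 71 matched ones) and changed the folds little (LTB log2 -2.05, KLRF1 log2 1.48). Most calls were lost there, while edgeR's prior degrees of freedom went from infinite to 8.29. With V segments of 1 UMI these were 8.66 and 415 genes passed. That setting had more blood cells with a pair (2834 and 1333) and more matched ones (274 and 450), so it does not bear on the loss. Cells and folds changed little in T-like cells, so the loss there goes with the change in prior degrees of freedom. Without the most frequent shared pair 0 genes passed (65 at an unadjusted p under 0.05), and KLRF1, CMC1, LILRB1 and GNLY had log2 -0.94, -0.58, -0.43 and -1.46 (LILRB1 with 3 UMIs in the matched cells, a ratio of 0.783, counting interval 0.159 to 2.35). When an expanded pair had to reach 2% of tumor cells, 6 and 1 matched blood cells were left, too few to place the genes. Fitted ratios of 12 of the 16 named genes changed sign, but 7 of these had 0 UMIs in the matched cells. Of the 7, GNLY was at least 15.9-fold lower there with a floor of 3 counts over the group (adjusted p = 0.00163). For the other 6 that floor sets no direction. The floor covers counting error only, not the spread of GNLY between cells. So few cells set no direction for GNLY either. None of the 12 but GNLY passed. Each pair test had 1 residual degree of freedom, and in blood edgeR's prior degrees of freedom were infinite, so the p-values lean on the spread shared by all genes.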

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

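No test was chosen after the results here were seen, and none of these differences was tested. Each stands out because the 2 patients went opposite ways between tumor and blood. The median log2 ratio of tumor over blood was 0.16 in patient 1 and -0.33 in patient 2 for chemokine and homing receptors. It was -0.25 and 0.29 for myeloid markers, -0.65 and 0.33 for NK markers, and -0.90 and 7.86 for melanocyte markers. In T-like clusters the NK markers went the same way in both patients (-0.41 and -0.35), while the other 3 lists did not (0.17 and -0.05 for chemokine and homing receptors, -2.43 and 0.32 for myeloid and -0.85 and 1.90 for melanocyte markers). The thinned share of cells with a UMI of GZMK, a granzyme gene, differed by 31.1 and -23.2 percentage points, and that of ITGAE, which encodes CD103, by -0.334 and 16.9 points. The ITGAE difference of patient 1 is within counting error, and without thinning the share was higher in tumor in both (19.1% against 17.6% and 43.4% against 19.96%). S100B had log2 -2.96 and 5.66, and the platelet gene PPBP -7.78 and 1.31, where the tumor library of patient 1 had 0 UMIs of PPBP and its value depends on the prior count. Melanoma-like cells were found in the tumor library of patient 2 alone.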

How the results depend on the processing

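Of the alternatives below, the mitochondrial share under 20%, the top 5% of doublet scores, T-like clusters with the replicate block, all those of the T-like comparison, T-like cells with a pair and leaving out the largest shared pair were chosen after seeing the data. The cause of a change was not tested unless stated. Genes higher and lower in tumor than blood (349 and 41) became 1200 and 467 with the replicate block, 1128 and 442 with DESeq2, 1016 and 367 in cells with CD8 and CD3 and no CD4, 1056 and 402 in T-like clusters, 1484 and 905 there with the replicate block, and 689 and 179 in thinned cells. They became 127 and 12 at a mean of 20 CPM or more, where 4812 genes were tested, and 214 and 13 without a cell filter. Library size alone gave 592 higher (35 lower) and moved the median log2 ratio of all genes to 0.30. Counts lower in tumor were 66 under a 5% mitochondrial share, 27 under 20% and 22 with V, D and J segments kept. Leaving out a library gave 0 to 2255 higher and 0 to 741 lower (edgeR, at least 1150 genes at an unadjusted p under 0.05), and 385 to 964 and 81 to 292 in T-like clusters, where DESeq2 called 616 lower and the replicate block 905. A tissue left with 1 library was assumed to vary like the other.

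Of the 23 lists 17 were called, 15 to 19 when a library was left out, 8 with fry, which added the fibroblast list, and 0 with an estimated correlation over all cells (lowest adjusted p 0.0826) and in T-like clusters (0.148). With an estimated correlation camera rested on 2 residual degrees of freedom, over all cells and in T-like clusters. The replicate block changed no list call over all cells, and in T-like clusters it lost the NK list (adjusted p = 0.110). With it all 52 called named genes kept the call and 6 others, given with their results, gained it; it changed no other call. In the other settings the granule list was gained under a 5% mitochondrial share, with the CD8 and CD3 gate, in T-like clusters with and without the replicate block and when thinned (adjusted p from 0.0119 to 0.0347), and the CD4 list was lost under 5% (0.115) and the platelet list when thinned (0.0542). None of 52 called genes named for tumor against blood changed direction where it was tested (50 in T-like clusters); the call was lost without the cell filter in 17, with V, D and J segments kept in 13, under 5% mitochondrial share in 12 of 51, under 20% in 9, without top doublet scores in 6, at 20 CPM in 6 of 40, by library size in 2 and with the gate in 1 of 51. Over these genes and those not called, 1075 of 1279 values kept their side of the threshold. Of 28 key gene shares, 10 differences moved without thinning, and CD8A came to 0.953 points.

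Genes higher and lower in tumor cells with an expanded pair (25 and 33) became 0 and 0 in edgeR without the replicate block (81 at an unadjusted p under 0.05), 0 and 2 with DESeq2 (154), 76 and 145 without a low-count filter, 105 and 217 with V segments of 1 UMI, 2 and 2 with 3 UMIs, 121 and 257 for pairs of 2% or more, 2 and 5 in T-like cells, and 50 and 64 without the largest pair. In blood (48 and 120) they became 0 and 0 without the replicate block (207), 6 and 5 with DESeq2, 29 and 113 without a low-count filter, 134 and 281 with 1 UMI, 0 and 3 for pairs of 2% or more (88), 3 and 2 in T-like cells, and 0 and 0 without the largest pair (65). With 3 UMIs the blood test could not be fitted, since no matched cell of patient 2 was left. RLE size factors and scrublet kept all counts within 1.5 times. Of 289 values of genes named for pairs, 102 lost the call and 17 changed direction. CXCL3 came to log2 -0.16 in T-like cells. For pairs of 2% or more, which left 6 and 1 matched blood cells, 7 genes had 0 UMIs in these cells, and their fitted log2 ratios (TRGC2 -7.67, SKAP2 -8.02, KLRF1 -9.98, XCL2 -9.43, LILRB1 -8.15, BBC3 -8.53 and GNLY -14.59) depend on the prior count and measure no fold. With a floor of 3 counts over the group GNLY was at least 15.9-fold lower (adjusted p = 0.00163, the only 1 of the 12 genes to pass), and the others have no direction. That floor covers counting error only, not the spread of GNLY between cells, so 6 and 1 cells do not place GNLY either. The other 5 gave CMC1 -2.20, SERINC5 0.80 (3 UMIs, ratio 2.68, counting interval 0.550 to 7.91), MAL 0.36, LTB 0.22 and CCR7 1.52. Without the largest pair KLRF1 had -0.94, CMC1 -0.58, LILRB1 -0.43 and GNLY -1.46.

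The share of blood cells with a tumor-expanded pair became 3.62% (patient 1) and 0% (patient 2) with 3 UMIs (0.285% and 3.52% for the other patient's pairs), 0.347% and 0.231% for pairs of 2% or more, where the other patient's pairs had 0.347% and 0%, 4.18% and 0.276% without the largest pair, and 33.8% with 1 UMI in patient 2. The share of tumor cells with an expanded pair became 19.9% and 46.8% with 1 UMI, 21.8% in patient 1 with 3 UMIs, and 7.95% and 45.1% for pairs of 2% or more. A pair was called in 28.6% and 11.99% of blood and 36.8% and 29.8% of tumor cells. Their medians were 3611.5, 3555, 3643 and 3629 UMIs per cell kept, in the same order. Depth per cell thus does not account for the differences between libraries.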

Other observations

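The tests of other cell types, free RNA and chance sharing were chosen after their results had been seen, while those of handling and carried-over blood cells were set before. A cluster of 215 cells led by KIT, FAM30A, TCF4 and SPINK2 had CD3 transcripts in 31.2% and CD8 transcripts in 14.4% of its cells. It held 3.73% and 1.72% of the UMIs of the tumor libraries and 0.228% and 0.0771% of those of the blood libraries (patients 1 and 2). In 10% or more of its cells 4 MAIT and 3 B or plasma markers were detected, but KIT, FAM30A, TCF4 and SPINK2 are in neither list, so it was left unnamed. A T-like cluster of 173 cells, led by AFF3, SESTD1, IL10 and POU2AF1, had CD3 transcripts in 99.4% but CD8 transcripts in 34.1% of its cells. It held 47 and 8 blood cells and 116 and 2 tumor cells.

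Part of the immediate early and heat shock genes were higher in tumor. The tables argue against cells of other types as the cause of the whole rise. In T-like clusters the called members kept 95.5% of their median log2 ratio. Other cells still gave part of it. Tumor UMIs over all cells and in T-like clusters were 8836 and 4068 for NR4A1, 4236 and 2040 for ATF3 and 165 and 40 for EGR3. For HSPA1A, HSPA1B and HSPA6 they were 18611 and 16106, 11262 and 9614, and 4047 and 3224. Handling that acts on every T cell remains open: T-like cells with a naive or memory marker and no exhausted marker kept 104% and 109.7% of the immediate early median in patients 1 and 2, and 58.6% and 97.3% of the heat shock median. A response to the tissue may give the same values and was not tested, because any difference in handling went with tissue in this design.

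Most genes of the exhaustion list were higher in tumor. The tables argue against cells of other types, since the list kept 109% of its median log2 ratio in T-like clusters. Free RNA as the cause of a part stays open. In other cells the genes had a median of 17.7% (quartiles 12.6 to 56.8) and 16.8% (14.8 to 32.8) of the UMIs per cell of T-like cells in the tumor libraries of patients 1 and 2. Both upper quartiles lie above the 25% set as a bound. The test set before, in CPM, gave 16.4% (11.6 to 52.5) and 5.83% (5.14 to 11.4), the latter below that bound, but the deep melanoma-like cells of patient 2 dilute free RNA in CPM, so UMIs per cell took its place. Among T-like cells all 21 genes of the list rose at a median log2 ratio of 5.53 (5.15 and 5.44 in patients 1 and 2), and a change of T cells in the tumor stays open as its cause, which was not tested.

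The share of blood cells with a pair expanded in the same patient's tumor was taken without the most shared pair. In patient 1 it was 4.18% (3.26 to 5.27), above the upper bound of 1.35% for the other patient's pairs. That background does not decide on chance sharing. It held 9 pairs against 15 in the full own set, and it was not matched to the V usage of patient 1. For pairs of 2% or more both shares were 0.347%. In patient 2 the share without the most shared pair was 0.276% against an upper bound of 3.92%, so chance sharing of other pairs remains possible there. Of the 26 tumor cells of the most shared pair in patient 1, 57.7% (36.9 to 76.6) had a UMI of an exhausted marker, against 11.7% in blood cells of that pair. This goes against all of them being carried-over blood cells, unless free tumor RNA gave these UMIs, which was not tested for these cells. The share was 78.7% (76.6 to 80.6) in other tumor cells with a pair, so carry-over of a part stays open. In patient 2 it was 38.5% of 13 cells (13.9 to 68.4), a range that holds the 15.7% of blood cells of the pair and lies below the 92.1% of other tumor cells, so carry-over may account for that pair. Clones shared between tumor and blood stay open, since a V pair is no clone.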
